A study of Homo sapiens with 4 samples.

How the data were processed

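RNA abundance was measured in AGS cells, a gastric adenocarcinoma line, after transfection with siRNA against YY1 or with a non-targeting control siRNA. Each group holds 2 arrays, which the labels call biological replicates 1 and 2. Per the labels' protocols, cells received 100 nmol of siRNA (the unit as the labels give it) with oligofectamine, and 500 ng of total RNA was converted to biotin-labelled sense cDNA and hybridised to a GeneChip Human Transcriptome Array 2.0. This array carries probes along the exons of coding and non-coding transcripts and summarises them per transcript cluster, the unit of the table rows analysed here.

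The deposited values are log2 expression values, 1 per row and array. The submitters' processing notes name RMA (background correction, quantile normalization and a robust summary of probes) and Affymetrix Expression Console 1.4.1.46, without saying which step did what. The log base is not stated in words. It was taken as log2 because RMA gives log2 values and the deposited range runs from 1.84 to 19.93. The highest value, 19.93, was shared by 220 to 256 rows per array and by 203 rows on every array, 12 of them with a gene symbol. At that value a row holds only a lower bound. The genome build behind the rows is not given in the sources used here, so no coordinates are printed, and the chromosome of a row was taken from its own identifier.

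The table holds 70523 rows. In the platform annotation 23781 rows had 1 gene symbol, 1543 had several and 45199 had none, and 1558 rows carried control-type identifiers. Symbols were updated through gene identifiers for 21497 of the rows with 1 symbol, were already current for 1974, were updated through a synonym for 306 and were kept as given for 4. For each of the 22411 genes, the row with the highest mean over the 4 arrays was used. Genes whose mean was at or above the median of all rows' means (3.10) were tested, which left 13260 genes. Of these, 5185 had a mean below 4 and so lay close to the background of the array. The number of arrays, not a read depth, limits the precision.

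YY1 siRNA arrays were compared with control siRNA arrays, two-sided, with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. The fit has 2 residual degrees of freedom per gene and 1.94 prior degrees of freedom. Errors given with a log2 difference are the moderated standard errors of this fit, and group means are given with their SD. Differences are YY1 siRNA minus control siRNA. Gene lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists tested. Camera compares a list with all other genes, so its direction can differ from the sign of a list's median. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, were run beside it. With an estimated correlation, camera's test rests on the 2 residual degrees of freedom, so it has little power over 32 lists. Each list's median was also ranked among 10000 random lists of the same size matched on mean level.

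The named genes follow a rule. They are YY1; the 12 genes with the largest rise and the 12 with the largest fall past the threshold, filled with the genes of smallest p in a direction that has fewer; and up to 4 members of each list with the smallest p, not all of which are reported here. Non-coding, olfactory receptor, immune segment and pseudogene symbols were left out of the second part, which removed 266 genes with an unadjusted p under 0.05. The test, the lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says that something was chosen after seeing the data.

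The alternatives were the replicate number as a block, eBayes without the trend or with robust moderation, the values quantile-normalized again, each array centred on its median, no filter or a filter at the 75th percentile of all rows' means (3.83), the mean of a gene's rows, all rows by identifier, other thresholds, and leaving out each array in turn. Centring used each array's median over the tested genes. A fit with a trend on local gene density removed from each array and a fit with the replicate numbers crossed were added after seeing the data. The density trend was removed together with its level, so this also removed each array's overall offset. Gene density was the number of protein-coding genes that start within 500 kb of a gene's start, with a coding gene counting itself. It was taken from an annotation of GRCh38.p14, used only for which genes neighbour each other. It was available for 13256 of the tested genes.

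The fit was tested on simulated data with the real means of the 13260 genes, 2 against 2 arrays and 200 changed genes, in 10 simulations per size. Each gene's spread was drawn from the prior distribution that the fit had estimated, so the recovery holds under the fit's own assumptions. It recovered 0.2% of genes changed by a log2 of 0.5, 46.5% at 1 and 88.9% at 2, with 0, 4 and 6.9 false calls on average. For the lists, 1 of 320 tests of simulated lists without a shift was called, and 10 of 10 with a shift of 0.3 were called. The simulated genes were independent of one another and the simulated arrays had no offsets.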

Results

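RNA was profiled on 4 arrays of AGS cells, an established line from a human gastric adenocarcinoma. The cells had been transfected with siRNA against YY1, a zinc finger transcription factor that activates or represses genes, or with a non-targeting control siRNA, with 2 arrays in each group. The comparison asks which transcripts differ after YY1 knockdown. Over the 13260 tested genes the array medians were 4.57 and 4.49 in the control group and 4.55 and 4.58 in the YY1 siRNA group. Across these genes Pearson's r was 0.996 between the control arrays, 0.997 between the YY1 siRNA arrays, and 0.992 to 0.994 between groups. The labels do not say what was separate between the replicates, so p-values measure only the spread between these arrays, and their small number limits the precision.

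YY1 itself, measured by row TC14000632.hg.1, was lower in both YY1 siRNA arrays than in both control arrays. Its log2 value was 8.95 and 9.35 in the control arrays (mean 9.15 ± 0.28, SD, n = 2) and 7.19 and 6.99 after YY1 siRNA (mean 7.09 ± 0.14, SD, n = 2). The log2 difference was -2.06 ± 0.18 (SE), a 4.17-fold lower level, with a 95% interval from -2.56 to -1.56. In the limma fit to the values as deposited its adjusted p was 0.134, which misses the threshold. With each array centred on its median YY1 fell by 2.10 (adjusted p = 0.0136).

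No gene passed the threshold in the limma fit to the values as deposited. The smallest adjusted p was 0.134, shared by 128 genes. At an unadjusted p under 0.05 there were 2346 genes, 1580 higher and 766 lower after YY1 siRNA, where chance alone would give 663; without 1 array there were 1945 and 2172 (control replicates 1 and 2) and 1343 and 1090 (YY1 siRNA replicates 1 and 2). The outcome depended on small offsets between arrays. With each array centred on its median over the tested genes, 260 genes passed, 141 higher and 119 lower. This centring shifted no array by more than 0.06. Control replicate 2 had the lowest of these medians, but the highest over all rows (3.16, against 3.09 to 3.11 in the other arrays). Centring on all rows would shift that array the other way and was not run. The share of higher genes among those with an unadjusted p under 0.05 was 67.3% as deposited and 54% after centring. Robust moderation gave 29 genes (14 higher, 15 lower) and a further quantile normalization gave 24 (6 higher, 18 lower), and all genes of both sets were among the 260.

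Among the 12 genes named for a higher level, TAF5, a subunit of the general transcription factor TFIID, differed most, by 1.64 ± 0.12 (SE). PSMB5, a catalytic subunit of the proteasome, differed by 1.45 ± 0.11, and NAE1, a subunit of the enzyme that activates NEDD8, by 1.37 ± 0.09. MMP1, the interstitial collagenase, was higher by 1.27 ± 0.08, with a mean of 8.53 ± 0.01 in the control arrays and 9.80 ± 0 after YY1 siRNA (SD, n = 2). TYMS, the thymidylate synthase, was higher by 1.20, CEP55, which acts in the last step of cell division, by 1.06, and the nucleolar proteins DDX21 and NOP58 by 1.05 and 0.93. The others were PM20D2 (1.27), RTKN2 (0.93), EI24 (0.67) and the translation termination factor GSPT1 (0.65). After centring all 12 of these genes rose, with adjusted p from 0.0116 for TAF5 to 0.0493 for EI24. Since no gene passed as deposited, these 12 and the 12 lower genes below were picked by smallest p, not by size of difference. They come from the same arrays, so their passing after centring is not independent evidence.

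Among the 12 genes named for a lower level, 3 belong to the pregnancy-specific glycoproteins, secreted members of the CEA family. PSG11 differed by -2.03 ± 0.16 (SE), PSG1 by -1.90 ± 0.08 and PSG6 by -1.70 ± 0.11. IFI27, an interferon-induced gene, differed by -1.70 ± 0.14, and MUC1, a membrane mucin of glandular epithelia, by -1.33 ± 0.09. VPS35L, a subunit of the endosomal retriever complex, was at -1.36, the matrix proteoglycan gene FMOD at -1.34, the apolipoprotein gene APOA2 at -1.25 and the epidermal gene DMKN at -1.18. Smaller differences were those of the metallothionein gene MT1H (-0.75), the quinone reductase gene NQO1 (-0.57) and GATM, an enzyme of creatine synthesis (-0.41). After centring 11 of these 12 genes fell, with adjusted p from 0.0104 for PSG1 and PSG6 to 0.0492 for NQO1, and GATM did not pass (adjusted p = 0.0769).

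**Figure D1:**
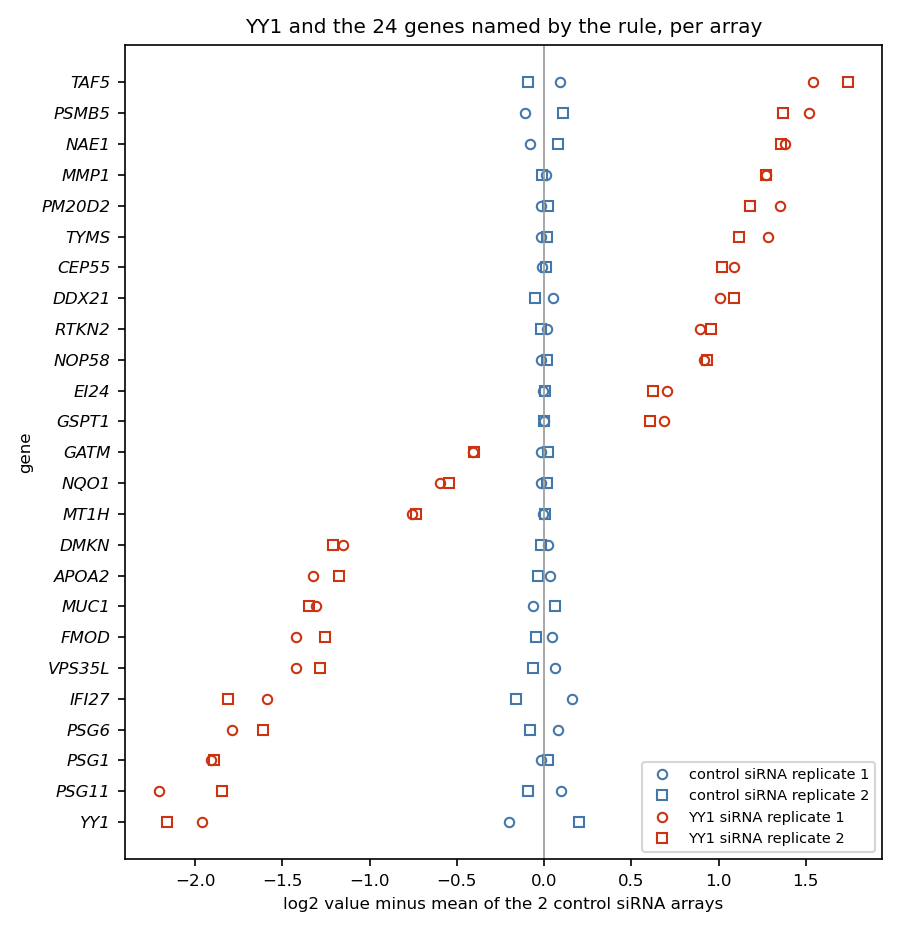
Log2 value of each array minus the mean of the 2 control siRNA arrays (horizontal axis) for YY1 and the 24 named genes (vertical axis); blue marks are control siRNA arrays, red marks YY1 siRNA arrays, circles replicate 1 and squares replicate 2. For every gene shown both YY1 siRNA arrays lie on one side of both control arrays, from TAF5 at a mean of 1.64 to YY1 at -2.06.

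Genes of DNA replication and mitosis were higher together after YY1 siRNA. Of 56 tested genes of S phase and replication, 54 were higher and 2 lower, with a median of 0.35. Beside TYMS, the subunit genes MCM6 and MCM7 of the replicative helicase were higher by 0.63 ± 0.09 (SE) and 0.56 ± 0.08. Of 61 genes of G2 and mitosis, 56 were higher and 5 lower, with a median of 0.33; cyclin A2 (CCNA2) was higher by 0.98 ± 0.09, the spindle protein gene NUSAP1 by 0.88, ECT2, which acts in cytokinesis, by 0.83 and the proliferation marker MKI67 by 0.68. Of 26 genes of homologous recombination and the Fanconi pathway, 21 were higher and 3 lower, with a median of 0.12, among them XRCC2 (0.71), BLM (0.52; also counted in the S phase list), RAD50 (0.46) and RAD51C (0.44).

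These 3 lists rose by camera, with adjusted p of 1.48e-12 for S phase, 1.02e-11 for mitosis and 0.00719 for recombination, and lay above zero in all 4 pairings of a YY1 siRNA with a control array. None of the 3 passed with an estimated correlation (adjusted p = 0.49 with an estimated correlation for S phase and for mitosis, and 0.814 for recombination). No single member passed over all genes; adjusted over the list alone, 27 S phase genes, 28 mitosis genes and 0 recombination genes were higher. Unadjusted p under 0.05 was reached by 34, 33 and 7 members, and after centring 3, 5 and 1 rose over all genes. The recombination list lost its call without YY1 siRNA replicate 2 (adjusted p = 0.0689). The mitosis median was 0.21 after a further quantile normalization (adjusted p = 1.09e-07), and the recombination median 0.07 with a gene-density trend removed (adjusted p = 0.0202).

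The proteasome showed the largest median of the 32 tested lists. Of 28 tested subunit genes, 26 were higher and 2 lower, with a median of 0.45. Beside PSMB5, the core subunit genes PSMA1, PSMB7 and PSMB2 were higher by 0.79 ± 0.10 (SE), 0.75 ± 0.09 and 0.47 ± 0.06. The list rose by camera (adjusted p = 1.91e-10), and not with an estimated correlation (adjusted p = 0.49 with an estimated correlation); fry's adjusted p was 0.0512. In this list 19 genes were higher when adjusted over the list alone, against 0 over all genes, 20 at an unadjusted p under 0.05 and 4 over all genes after centring.

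Genes for making and processing RNA and ribosomes were higher by less. Of 45 genes of ribosome biogenesis and MYC targets, 36 were higher and 7 lower, with a median of 0.15; beside NOP58, the ornithine decarboxylase gene ODC1 was higher by 0.97 ± 0.09 (SE), WDR43 by 0.65 and the chaperonin gene HSPD1 by 0.55. Of 72 genes of the mitochondrial ribosome, 50 were higher and 19 lower, with a median of 0.11, led by MRPS10 at 1.08 ± 0.11, MRPL47 at 0.68, MRPL50 at 0.55 and MRPS30 at 0.54. Of 42 spliceosome genes, 33 were higher and 9 lower, with a median of 0.15, among them SF3B3 (0.52), SF3A3 (0.42), SNRPB2 (0.37) and HNRNPM (0.34). The 3 lists rose by camera (adjusted p = 0.001, 0.0138 and 0.0114), each with adjusted p = 0.49 with an estimated correlation.

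Adjusted over the list alone, 6 genes of ribosome biogenesis, 1 of the mitochondrial ribosome and 2 of the spliceosome were higher, against 0 in each over all genes as deposited; after centring 2, 3 and 0 rose over all genes. At an unadjusted p under 0.05, 11 genes of ribosome biogenesis and 11 of the spliceosome were higher, and in the mitochondrial ribosome 19 were higher and 3 lower. The median of ribosome biogenesis was 0.09 without control replicate 2 (adjusted p = 0.00398). The call was lost for ribosome biogenesis after a further quantile normalization (median 0.06, adjusted p = 0.0579), for the mitochondrial ribosome without control replicate 1 (0.201) or YY1 siRNA replicate 2 (0.0542), and for the spliceosome after quantile normalization (median 0.07, 0.401), with the strict filter (0.0756) and without control replicate 1 (0.054) or YY1 siRNA replicate 2 (0.0542).

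Interferon-response genes were lower together after YY1 siRNA. Of 41 tested genes, 34 were lower and 6 higher, with a median of -0.20. IFI27 differed most, and IFIT3, an antiviral RNA-binding protein, and HLA-C, which presents antigen, were at -0.58 ± 0.09 (SE) and -0.57 ± 0.09. IFI6 stood at the highest value of the table, 19.93, in both control arrays and at 19.82 and 19.85 after YY1 siRNA, so its difference, -0.10 as measured, is only a bound. The list fell by camera (adjusted p = 4.11e-08), in all 4 pairings of arrays, but not with an estimated correlation (adjusted p = 0.719 with an estimated correlation). Adjusted over the list alone 5 genes were lower, against 0 over all genes and 15 at an unadjusted p under 0.05; after centring 3 fell over all genes. IFI6 is 1 of the 15, and without it 4 and 14 genes were lower. The list without IFI6 still fell by camera (adjusted p = 1.74e-07), but not with an estimated correlation (adjusted p = 0.76 with an estimated correlation). Without control replicate 1 the median was closer to zero, at -0.10, and the list still fell (adjusted p = 4.84e-05).

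Genes of the Wnt pathway, of gastric and intestinal identity and of epithelial junctions were lower by small amounts. Of 36 Wnt genes 22 were lower and 13 higher, with a median of -0.10. NKD1, a feedback inhibitor of the pathway, was at -1.60 ± 0.17 (SE), cyclin D1 (CCND1) at -0.51 and the receptor-removing ligase RNF43 at -0.46, while APC, part of the complex that degrades beta-catenin, was at 0.36. Of 22 lineage genes 15 were lower and 7 higher, with a median of -0.05; beside MUC1, the pioneer factor FOXA1 was at -0.78 ± 0.07, the transcription factor SOX2 at -0.49 and the intestinal cadherin CDH17 at 0.33. Of 33 junction and keratin genes 21 were lower and 11 higher, with a median of -0.04, among them TJP3 (-0.65), KRT19 (-0.45), CLDN1 (-0.28) and CLDN2 (-0.20).

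The 3 lists fell by camera (adjusted p = 0.00661 for Wnt, 0.0345 for lineage and 0.0435 for junctions), and none passed with an estimated correlation (adjusted p = 0.918, 0.49 and 0.918 with an estimated correlation). Adjusted over the list alone 1 Wnt gene was lower, 2 lineage genes were lower and 1 higher, and 0 junction genes passed, against 0 in each over all genes as deposited. After centring 1 Wnt gene (NKD1), 2 lineage genes (MUC1 and FOXA1) and 1 junction gene (TJP3) fell over all genes. Unadjusted p under 0.05 was reached by 6 lower and 2 higher Wnt genes, 4 lower and 1 higher lineage genes and 3 lower junction genes. Without the filter on dim rows all 3 calls were lost (adjusted p = 0.0668, 0.118 and 0.107), with a median of -0.04 for Wnt and -0.02 for lineage. The lineage call was also lost on ranks (0.0712), with the replicate numbers crossed (0.0886) and without any one of the 4 arrays (0.051 to 0.0802). The junction call was also lost on ranks (0.0509), with the numbers crossed (0.0768), with a gene-density trend removed (0.0578), and without control replicate 1 (0.254) or YY1 siRNA replicate 2 (0.258). Without control replicate 1 the Wnt median was -0.05 (adjusted p = 0.0415) and the junction median -0.02. Without control replicate 2 the junction median was -0.07, and without YY1 siRNA replicate 2 it was -0.005 and the lineage median -0.09. Over all settings the medians ranged from -0.17 to -0.04 for Wnt, from -0.11 to -0.02 for lineage and from -0.10 to -0.01 for junctions.

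**Figure D2:**
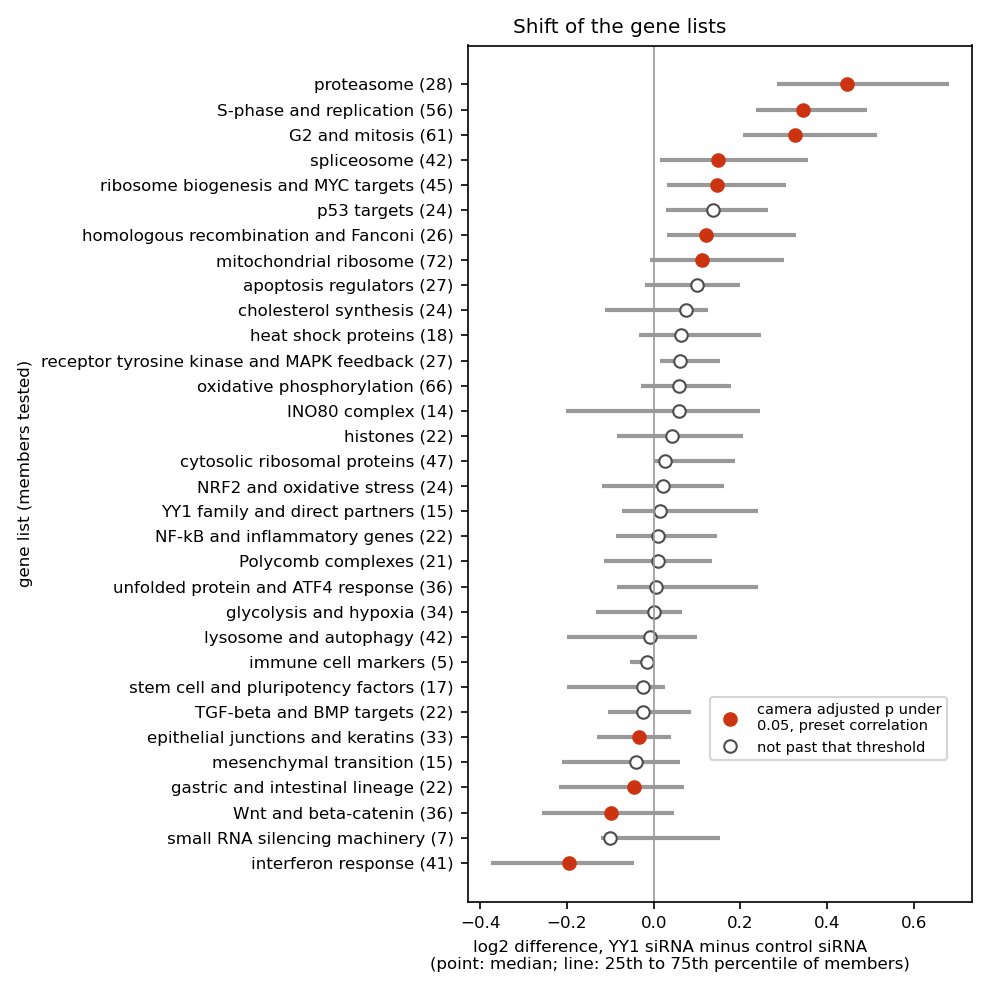
Median log2 difference (horizontal axis, YY1 siRNA minus control siRNA) of the tested members of each gene list (vertical axis, number of members in parentheses), with a line from the 25th to the 75th percentile of the members. Filled red points are the 11 lists with a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation or with fry, 0 lists passed. The proteasome lies highest at 0.45 and the interferon response lowest at -0.20.

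The lists of YY1's own complexes were not called by camera. Of 15 tested genes in the list of YY1, its relatives and its direct partners, 8 were higher and 7 lower (camera adjusted p = 0.997). YY1 itself, the siRNA target at -2.06, is 1 of the 7. The list was not tested without YY1, so this test does not show whether the partners shifted. The cofactor HCFC1 was at 1.01 ± 0.23 (SE), the deacetylase HDAC2 at 0.45 and the insulator protein CTCF at 0.27. In the INO80 remodelling complex (14 genes, adjusted p = 0.635) the deubiquitinase UCHL5 was at 0.84, ACTR5 at 0.34, RUVBL1 at 0.30 and INO80C at 0.23. Of 21 Polycomb genes (adjusted p = 0.773) RING1 and PCGF2 were at -0.49 and -0.69 and MTF2 and PCGF3 at 0.48 and 0.38. Of 7 genes of small RNA silencing (adjusted p = 0.773), DICER1 was at 0.49 and TARBP2 at -0.22. Adjusted over the list alone only YY1 in the first list and 1 higher gene in the INO80 complex passed, against 0 over all genes as deposited; after centring YY1 and RING1 fell and UCHL5 rose over all genes.

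Further lists did not pass by camera as planned, although 4 of them did in some other settings. Among p53 targets 19 of 24 genes were higher, with a median of 0.14 (adjusted p = 0.0748); the phosphatase gene PPM1D was at 0.68, RRM2B at 0.53 and CCNG1 at 0.34, and TP53I3 was at -0.56. The p53 list rose without the filter on dim rows (adjusted p = 0.0109) and without control replicate 1 (0.0354), but not with an estimated correlation in these settings (adjusted p = 0.739 and 0.8 with an estimated correlation). Of 42 lysosome and autophagy genes 22 were lower (adjusted p = 0.0929), with the lysosomal proteases CTSH and CTSA at -0.82 and -0.64, GAA at -0.47 and PSAP at -0.39. This list fell after a further quantile normalization (adjusted p = 0.0115), with the strict filter (0.0468, at a median of only -0.01) and without control replicate 2 (0.0367). None of the 3 calls held there with an estimated correlation (adjusted p = 0.605, 0.962 and 0.837 with an estimated correlation). Of 24 genes of the NRF2 response (adjusted p = 0.773), HMOX1, CAT and ABCC3 were, beside NQO1, at -0.67, -0.38 and -0.39. In oxidative phosphorylation (66 genes, adjusted p = 0.481) CYCS, NDUFB5 and NDUFA2 were at 0.61, 0.52 and 0.42 and ATP5PD at -0.39. Without control replicate 2 this list and the cytosolic ribosomal proteins rose (adjusted p = 0.0399 and 0.0309), but not with an estimated correlation (adjusted p = 0.837 for both with an estimated correlation). Of 15 genes of mesenchymal transition (adjusted p = 0.212), CCN2, TGFB1 and COL6A1 were at -0.77, -0.63 and -0.26 and ITGB1 at 0.24. Among 17 stem cell factors (adjusted p = 0.393) 11 were lower and 6 higher, with a median of -0.025. The Notch ligand JAG1 was at 0.99 and ITGA6 at 0.17, and SOX9 was at -0.665 and SOX2 at -0.49.

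In the unfolded protein and ATF4 response (36 genes, adjusted p = 0.773), the serine synthesis gene PSAT1 was at 1.06, MTHFD2 at 0.58, AARS1 at 0.52 and PDIA4 at -0.55. The cholesterol synthesis genes (24 genes, adjusted p = 0.722) SQLE, HMGCS1, NSDHL and EBP were at 0.59, 0.47, 0.43 and 0.42. Of 34 glycolysis and hypoxia genes (adjusted p = 0.443), ERO1A, EGLN1 and HK1 were at 0.78, 0.61 and 0.33 and EGLN3 at -0.42. PTGS2, the inducible cyclooxygenase, was at 0.91 in the NF-kB list (22 genes, adjusted p = 0.773), and HSPH1 at 0.63 among heat shock proteins (18 genes, adjusted p = 0.601). The apoptosis regulators (27 genes, adjusted p = 0.283), histones (22 genes, 0.722), cytosolic ribosomal proteins (47 genes, 0.391), TGF-beta and BMP targets (22 genes, 0.566) and kinase feedback genes (27 genes, 0.520) had medians of 0.10, 0.04, 0.03, -0.03 and 0.06.

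Adjusted over the list alone, 4 p53 targets, 3 genes of the ATF4 response, 2 of oxidative phosphorylation and 1 each of the cholesterol, stem cell and heat shock lists were higher. By the same adjustment 1 gene was lower in each of the p53, lysosome, NRF2, oxidative phosphorylation, mesenchymal and ATF4 lists, and 0 passed in the remaining lists of these paragraphs. Over all genes 0 passed in each as deposited; after centring 2 lysosome, 2 NRF2, 1 p53 and 1 mesenchymal gene fell, and 1 each of the oxidative phosphorylation, stem cell, NF-kB and ATF4 lists rose. The median was positive and the camera direction downward for the Polycomb, NF-kB and NRF2 lists, and the mean of the NRF2 list was below zero (-0.003). For small RNA silencing the median was -0.10 and the mean 0.03. For the list of YY1 and its partners, which includes YY1 at -2.06, the median was 0.02 and the mean -0.02.

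Few markers of other cell types were measured above background. The median level was lowest for the 10 endothelial markers (2.94) and highest for the 14 immune markers (3.02), with that of the 11 fibroblast markers between them. PDGFRA reached 6.35 and LYZ, which encodes lysozyme and is also made by gastric epithelium, 18.4; no other marker reached a mean of 5, and CD68 stood at 4.78 in the control arrays and 4.76 after YY1 siRNA. LYZ differed between groups by -0.08 and PDGFRA by -0.16, which was -0.085 without control replicate 1. The other 2 tested fibroblast markers were lower too, COL1A1 by -0.165 and DCN by -0.605. DCN lay close to background, with means of 3.555 in the control arrays and 2.95 after YY1 siRNA. Only 3 fibroblast and 3 endothelial markers passed the filter, too few for a test, and the 5 immune markers gave a camera adjusted p of 0.513, with a median of -0.02 and a mean of 0.001. LYZ passed, at a lower level, when adjusted over the list alone; over all genes its adjusted p was 0.737 with robust moderation and 0.488 after centring.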

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

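The fit with gene density removed and the fit with crossed numbers were chosen after seeing the data; the other settings were planned. Against 0 genes in the limma fit as deposited (2346 at an unadjusted p under 0.05), 260 genes passed with each array centred on its median, 29 with robust moderation, 24 quantile-normalized again, 155 with gene density removed (81 higher, 74 lower, 152 of them among the 260), and 459 at an unadjusted p with a 1.5-fold difference (301 higher, 158 lower). Centring raised the prior degrees of freedom from 1.94 to 4.23. Removing the density trend also removed each array's offset, so its 155 genes and its call of YY1 are not evidence apart from centring. Every other setting gave 0 genes, as did each fit without 1 array. YY1 was lower in every setting, from -1.86 to -2.26 without 1 array, and passed after centring (-2.10, adjusted p = 0.0136), with robust moderation (-2.06, 0.0392), quantile-normalized again (-2.18, 0.0451) and with gene density removed (-2.13, 0.0177). Its adjusted p ranged up to 0.569.

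The labels do not say that a replicate number marks a shared day. The deviations of same-numbered arrays had a correlation of -0.142 over genes. With 2 arrays per group each group gives a single contrast, so this value cannot tell whether a number marks a shared day or culture. With the replicate block 0 genes passed, 1636 had an unadjusted p under 0.05, and YY1 was at -2.06; all 11 list calls were shared. With the numbers crossed 0 genes and 9 lists passed.

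The 11 lists called by camera fell to 0 with an estimated correlation and to 0 with fry. The loss with an estimated correlation does not by itself show correlated genes. For ribosome biogenesis the estimated correlation was -0.014, under the preset 0.01, yet its unadjusted camera p rose from 0.000157 to 0.0453. With 2 residual degrees of freedom this test therefore cannot decide whether the shifts hold. Without 1 array the count ranged from 6 (without YY1 siRNA replicate 2) to 13 (without control replicate 2). S phase, mitosis, proteasome and interferon kept their calls in every camera setting with the preset correlation. The estimated correlation lay above the preset 0.01 for S phase (0.122), mitosis (0.092), proteasome (0.042) and interferon (0.266). It was also above for Wnt (0.216), junctions (0.172), recombination (0.131) and spliceosome (0.015), and below for the mitochondrial ribosome (0.006) and lineage (-0.012). Where the true correlation exceeds the preset, camera's p at the preset is too small. Over named genes and alternatives, 2102 values kept direction and side of the threshold, 116 passed in addition and 7 reversed. No named gene passed as deposited, so none could lose a call, and keeping the side means that it again did not pass. The reversed values were near zero, in markers of other cell types: CLDN5 (-0.01 after centring, and -0.06 to 0.11 without 1 array), CD68 (0.058 with gene density removed, and -0.175 to 0.145 without 1 array), EMCN (-0.13 to 0.03 without 1 array) and CD3E (-0.14 to 0.03 without 1 array). For these results the cause was not tested. Of the tested genes 5185 had a mean below 4, close to background, which limits what their differences show.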

Other observations

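The lists of this part and the tests of arrays taken 1 at a time, of shared probes, of a trend that separates replicates and of other splits were chosen after the data were seen; the matched lists and the tests of gene density had their outcomes written down before they were run. All 10 tested pregnancy-specific glycoprotein genes, which lie together on chromosome 19, were lower after YY1 siRNA, each at an unadjusted p under 0.05, with a median of -1.19. The lists of this part were put together after members of them had been seen among the genes with the smallest p, so no test of the lists is given. Beside PSG11, PSG1 and PSG6, PSG7 was at -1.34, PSG5 at -1.24, PSG9 at -1.14 and PSG4 at -1.06. The 6 plasma protein genes of liver type were lower too, with a median of -0.49; the fibrinogen chain FGA was at -1.92 and FGG at -0.40. All 14 metallothionein genes were lower, 5 of them at an unadjusted p under 0.05, with a median of -0.43, among them MT1F at -1.28. These include pseudogenes such as MT1DP, and rows close to background, such as MT4 and MT3 (control means 3.155 and 3.725). Probes shared between members were not checked, so the number of separate decreases is not known. No member of these lists passed over all genes with the values as deposited. After centring 9 of the glycoprotein genes, 2 of the plasma protein genes and 2 of the metallothionein genes fell, and with robust moderation 3, 2 and 1 passed.

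The 7 tested genes of the CCT chaperonin, which folds actin and tubulin, were all higher, with a median of 0.49 and CCT8 and CCT6A at 0.67 and 0.63; 5 reached an unadjusted p under 0.05, 0 passed over all genes as deposited and 1 rose after centring. Of 27 genes of neddylation and cullin ligases 19 were higher, with a median of 0.15; beside NAE1, NEDD8 was at 1.28 and the scaffold CUL1 at 0.81. Of these 11 were higher at an unadjusted p under 0.05, 0 passed over all genes as deposited, 4 rose after centring and 1 passed with robust moderation. Of 170 small nucleolar RNAs 97 were lower and 71 higher, with a median of -0.08; 21 were lower and 7 higher at an unadjusted p under 0.05, 0 passed as deposited and 3 fell after centring. MYL9, a myosin light chain outside the naming rule and picked after its values were seen, was at 2.54, with 11.4 and 10.9 in the control arrays and 13.8 and 13.6 after YY1 siRNA (adjusted p = 0.134 as deposited, 0.0116 after centring).

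The joint higher level of the S phase, mitosis and proteasome lists was set against 3 technical explanations. A shift that depends on signal level is argued against as the whole cause by matched lists. The lowest of the 3 medians lay at percentile 100 of 10000 lists matched on mean level. After a further quantile normalization the medians fell from 0.345 to 0.265 (S phase), 0.325 to 0.206 (mitosis) and 0.445 to 0.336 (proteasome), so a part that depends on signal level stays open. A gene-density trend of the size fitted is argued against as the whole cause. The lists kept at least 0.897 of their medians once this trend and the array offsets were removed. Centring alone gave medians of 0.31, 0.29 and 0.41, near the 0.310, 0.292 and 0.401 with density removed. The fitted trend was too small for its removal to take much from these lists. A single deviating array is argued against as the whole cause by the medians without 1 array. These ranged from 0.31 to 0.40 (S phase), 0.28 to 0.395 (mitosis) and 0.39 to 0.49 (proteasome). Over the 3 lists and 4 pairings of arrays 12 of 12 medians were positive, but the pairings reuse the same 4 arrays and count only the sign. No test here separates the loss of YY1 from other effects of the siRNA or from a difference in growth between cultures. The siRNA sequence or pool is not given, so all of these stay open, for every gene and list.

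Genes on chromosome 19 were lower, with a median of -0.05, the lowest of the chromosomes. The median difference from the other genes was -0.08 (permutation p = 1e-04 over genes, the smallest the permutations can give; genes are not replicates), and 104 of 935 genes (11.1%) were lower at an unadjusted p under 0.05, against 5.31% of 12216 others. A technical trend between arrays is a candidate explanation. The same contrast differed by 0.06 between the control arrays. In size this is 0.857 of the mean difference between groups over the 4 pairings of arrays, which was -0.07. Off chromosome 19, genes with a density of at least 19 protein-coding genes within 500 kb differed from those with at most 6 by -0.055 (medians -0.005 and 0.05). That lies between the bounds set for and against a gene-density trend, so this trend and a change in chromosome 19 genes cannot be told apart. With density removed the difference was -0.02. The median of chromosome 19 was then -0.021 and no longer the lowest, with chromosome X at -0.027 and chromosome 13 at -0.026.

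The lower level of the pregnancy-specific glycoprotein genes kept 0.989 of its median with the density trend removed, which argues against that trend as its cause. These genes are highly similar in sequence, and all 10 members were lower, as probes that read several of them could also give. How many members differ, as opposed to 1 or a few read by shared probes, therefore cannot be told apart here.

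Of the 3 ways to split the 4 arrays into pairs, the real one gave 2346 genes at an unadjusted p under 0.05 and the highest other 381, so 1 of 3 splits gave as many. Without 1 array the real split gave from 1090 to 2172. These splits are too few for a share under 0.05.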
